A study of Mus musculus with 12 samples.

How the data were processed

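Chromatin immunoprecipitation and sequencing (ChIP-seq) of histone marks was done in mouse melanoma cells, per the labels' protocols. The cells came from ear tumours of iBIP mice, which carry a melanocyte-specific, tamoxifen-activated Cre and an inducible oncogenic BRAF allele, among other engineered alleles. Tumours were started with doxycycline and 1 uM of 4-hydroxytamoxifen on the ears. WT cells had intact Kmt2d and mutant cells had both Kmt2d copies conditional. Chromatin was sheared by sonication, libraries had 10 PCR cycles, and fragments of about 200 to 500 bp were retained, per the labels.

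The series has 12 samples: 5 marks and an input in each of 2 genotypes, with 1 library per genotype and mark. The marks were H3K4me1, H3K27ac, H3K4me3, H3K79me2 and H3K27me3. The series text gives 6 modifications, of which 5 were analysed here. The 2 input libraries were not used here. Groups were taken from the sample titles.

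The values start from the 10 peak lists the authors deposited, each called in a single library. Bowtie, MACS, MACS2 and deepTools and the mouse build mm9 are named in the submitters' processing notes, without versions or roles. The lists of H3K4me1, H3K27ac and H3K4me3 are BED lists whose names carry the word MACS; their deposited score per peak reads as 10 times the −log10 of the p-value. The lowest score in these lists was 90, which is a p of 1e-09. In these lists 1508 peaks had a score of exactly 3100 and 234 a higher one, so the score does not rank the strongest H3K27ac and H3K4me3 peaks. No H3K4me1 peak reached 3100, the highest H3K4me1 scores being 2572 in WT and 1307 in the mutant. The lists of H3K79me2 and H3K27me3 are MACS2 broad peaks. Each of them gives, as the authors deposited it, a fold enrichment (ratio), a −log10 p and a −log10 q per peak, and a score that is 10 times the −log10 q. The lowest −log10 p there was 5.00, which is a p of 1e-05. Scores and folds are the authors' own values, and were used to describe, rank or filter peaks within a list. The exception is peak width, where WT and mutant peaks were paired by scores within 10% of each other, across lists of unknown depth.

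Read depth is unknown, since a peak list carries no read count, so the share of a difference that depth accounts for cannot be read from the lists. A peak missing from a list means that no peak passed the authors' threshold there, not that the mark was absent. With no replicates, no test between genotypes was made and no p-value is given. Shares of peaks carry exact (Clopper-Pearson) 95% binomial intervals. These cover counting error only, and neighbouring peaks are not independent.

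Peaks were shared when they overlapped by at least 1 bp. The overlap that position alone gives was described by placing the other genotype's peaks at random within each chromosome 100 times. Active distal elements were H3K27ac peaks that overlapped H3K4me1 and no H3K4me3 in the same genotype. Bivalent regions were H3K4me3 peaks that overlapped H3K27me3. Large H3K27ac domains were peaks joined across gaps of up to 12500 bp that spanned at least 20 kb. Broad H3K4me3 peaks were at least 4000 bp wide. Stretches without any mark were autosomal gaps of at least 200 kb between peaks of all 5 marks in a genotype; those with peaks of at least 3 marks in the other were described. For a comparison of peak classes at like strength, shares were averaged over 5 equal groups by score. For chromosome X the 5 groups were set by the H3K27ac scores of its own peaks.

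Regions were named by a rule. Per mark and genotype it took the 4 peaks with the best score and no peak of the other genotype within 1000 bp, the MACS2 marks being ranked by −log10 q. It also took up to 5 of the largest H3K27ac domains, and the 5 longest H3K79me2 and H3K27me3 peaks, with no overlapping peak of the other genotype. The 5 longest stretches without any mark were added. Coordinates are those of the deposited lists on mm9, counted from 1. The only gene table used here is on another mouse build, so regions carry no gene names, and the 12 gene lists drawn up for this comparison were not run.

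The alternatives were a stricter threshold (MACS score of at least 100, −log10 q of at least 3), merging peaks within 1000 bp, autosomes only, cover of at least 50% of a WT peak, peaks within 1000 bp counted as shared, lists cut to the same number of strongest peaks, a stitching distance of 5000 bp and a width of 6000 bp for broad H3K4me3. These, the rule and the classes were fixed before the data were examined. A still stricter threshold (score of at least 200, −log10 q of at least 5), the distal count without the H3K4me1 libraries, the WT H3K4me1 list limited to its strongest peaks, a distance of 10000 bp for named regions, and 20 score groups for H3K4me1 sites by class were chosen after seeing the data.

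Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap code was tested on simulated lists with known shared shares, where the largest error over 15 cases was 0.495 percentage points. It gave 0 differences from bedtools 2.31.1 in 182 comparisons of the real lists.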

Results

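Histone marks were mapped by ChIP-seq in melanoma cells of the iBIP mouse model, with KMT2D intact (WT) or mutant. KMT2D is a methyltransferase that places H3K4me1 at enhancers. H3K4me1 marks enhancers, H3K27ac active enhancers and promoters, H3K4me3 promoters, H3K79me2 transcribed gene bodies, and H3K27me3 regions silenced by Polycomb. Each genotype had 1 library per mark, so no difference below has a replicate check, and read depth is unknown. The question was which parts of the chromatin landscape differ between WT and mutant cells.

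H3K4me1 had the largest difference between the lists. The WT list held 15981 H3K4me1 peaks over 24.5 Mb and the mutant list 5358 peaks over 7.34 Mb. H3K27ac and H3K4me3 differed far less: H3K27ac peaks numbered 25060 in WT and 22343 in the mutant, and H3K4me3 peaks 14723 and 13691. The covered length of both marks was slightly greater in the mutant, at 54.0 against 53.0 Mb for H3K27ac and 32.4 against 30.8 Mb for H3K4me3. H3K79me2 covered 91.3 Mb in WT and 75.2 Mb in the mutant. H3K27me3 went the other way, with 27.8 Mb in WT and 37.8 Mb in the mutant.

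**Figure D1:**
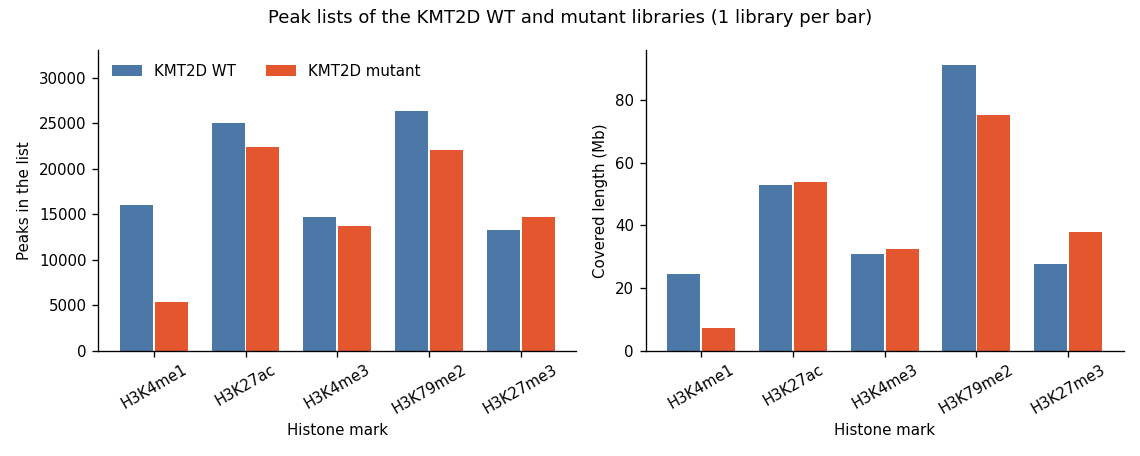
Bars give the number of peaks (left) and the covered length in Mb (right) for each histone mark in the WT and mutant libraries, 1 library per bar. The H3K4me1 bars stand at 15981 and 5358 peaks, while H3K27ac and H3K4me3 bars are of similar height.

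For H3K4me1, the mutant list had 0.335 times as many peaks and 0.300 times the covered length of the WT list. Of the WT H3K4me1 peaks, 77.0% (95% interval 76.3 to 77.6, 12300 of 15981) had no mutant peak. Of the mutant H3K4me1 peaks, 27.9% (26.7 to 29.1) had no WT peak. These shares depend on the longer WT list: between the 5358 strongest peaks of each list, 43.0% (41.7 to 44.3) of the WT and 49.3% (48.0 to 50.7) of the mutant H3K4me1 peaks had a peak of the other genotype. WT H3K4me1 peaks without a mutant peak had a median width of 1140 bp, against 1760 bp for those with one. Among the strongest 10% of WT H3K4me1 peaks 68.5% (66.2 to 70.8) had a mutant peak, and among the weakest 10% 8.76% did. Random placement gave 0.696% for all WT H3K4me1 peaks. With a still stricter score threshold the ratio was 0.189 for H3K4me1 peak counts and 0.180 for covered length.

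**Figure D2:**
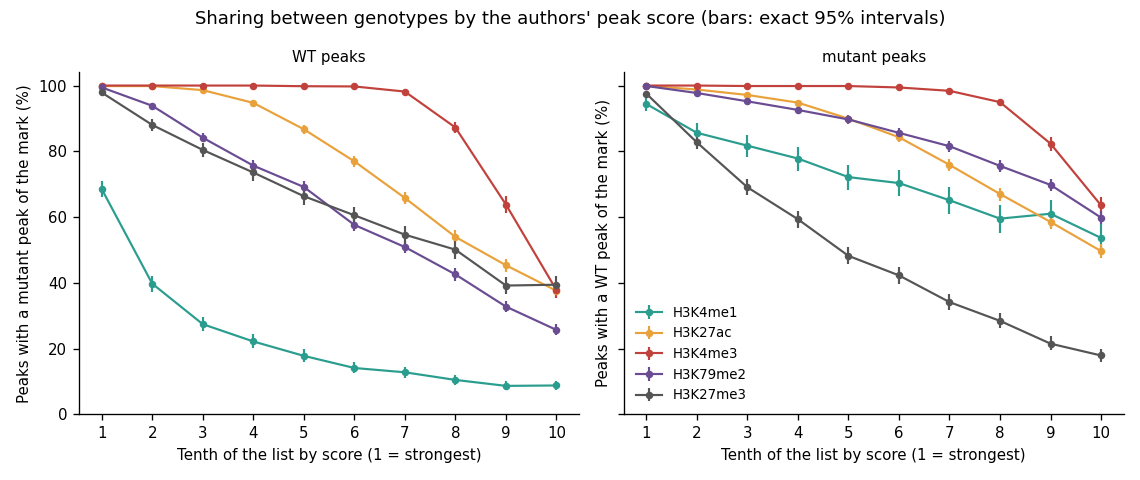
Each point is the share (%) of peaks with a peak of the same mark in the other genotype, with the list divided by score into 10 equal parts from the strongest (1) to the weakest (10), for WT peaks (left) and mutant peaks (right); vertical bars are exact 95% binomial intervals. WT H3K4me1 starts at 68.5% in the strongest part, where WT H3K4me3 stands at 100%.

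The WT H3K4me1 peak with the best score and no mutant peak nearby lay on chromosome 15 from 79263116 to 79271134 (score 1775). The mutant had H3K27ac over 4173 bp, H3K4me3 over 1366 bp and H3K79me2 over 7041 bp of this region. The next H3K4me1 peaks were on chromosome 11 from 32435721 to 32443181, and on chromosome 14 from 26341092 to 26348486 and from 26418917 to 26423649. Mutant H3K27ac covered 7185, 7395 and 4671 bp of these, nearly their full lengths of 7461, 7395 and 4733 bp. All 4 regions thus had H3K27ac in both genotypes; 3 of them had a mutant H3K4me1 peak within 10000 bp. The strongest H3K4me1 peak of the mutant without a WT peak nearby was on chromosome 9 from 90160024 to 90162693 (score 569.2). WT cells had H3K27ac over 1373 bp and H3K79me2 over all 2670 bp of it, and 4 WT H3K4me1 peaks within 10000 bp. On chromosome 11 from 115078507 to 115081862, both H3K4me1 and H3K27ac were in the mutant lists and no WT list had a peak, with 1 WT H3K4me1 peak within 10000 bp.

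Active distal elements, which carry H3K27ac and H3K4me1 but no H3K4me3, numbered 5003 in WT and 1934 in the mutant, a ratio of 0.387. In the mutant, 51.4% (50.01 to 52.8) of the WT elements still had an H3K27ac peak but neither H3K4me1 nor H3K4me3. Another 27.4% (26.2 to 28.6) had both H3K27ac and H3K4me1, 2.94% had H3K4me1 alone of these marks, 3.72% had H3K4me3, and 14.6% (13.6 to 15.6) had none of the 3 marks. Elements without mutant H3K4me1 had mutant H3K27ac in 78.3% (76.9 to 79.7) of cases, and elements with mutant H3K4me1 in 90.8% (89.3 to 92.2). At like H3K27ac score this difference was -6.72 percentage points (-8.83 to -4.61). H3K27me3 was found in the mutant at 49 of the 5003 elements. The ratio was 0.906 when H3K4me1 was not required, 0.758 with the WT H3K4me1 list limited to its strongest peaks and 0.226 with the still stricter threshold.

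**Figure D3:**
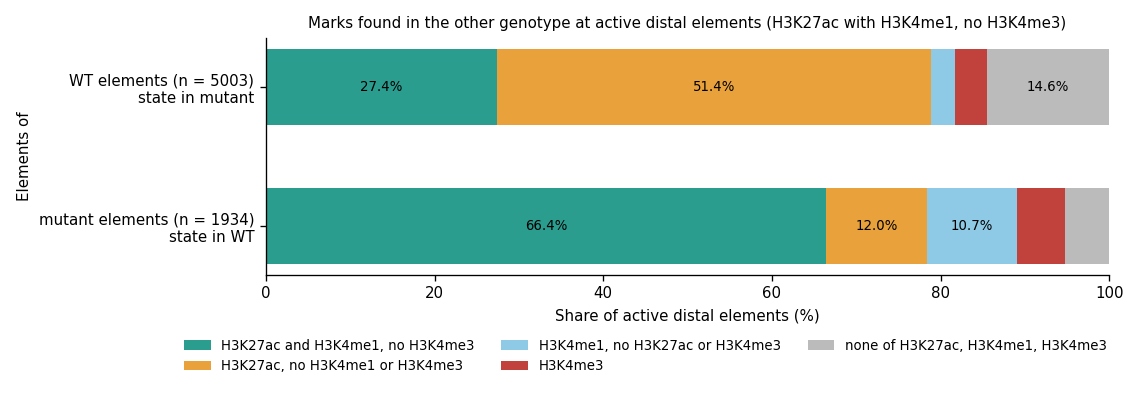
Stacked bars give the share (%) of active distal elements of each genotype by the marks found there in the other genotype. H3K27ac without H3K4me1 is the largest part of the WT bar (51.4%), and H3K27ac with H3K4me1 the largest part of the mutant bar (66.4%).

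Over all 12300 WT H3K4me1 peaks with no mutant peak, 50.1% (49.2 to 51.0) overlapped mutant H3K27ac and 51.2% had overlapped WT H3K27ac. Where WT H3K27ac was present, 84.2% (83.3 to 85.1) of these sites had mutant H3K27ac. WT H3K4me1 peaks with no H3K27ac, H3K4me3 or H3K27me3 numbered 6061, and 12.0% (11.2 to 12.8) of them had a mutant H3K4me1 peak. WT H3K4me1 peaks with H3K27ac had one in 31.1% (30.2 to 32.1) of cases. The class without these 3 marks, which could still carry H3K79me2, had the lower share in each of the 5 score groups, with 35.4% against 56.3% for distal H3K27ac sites in the strongest.

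H3K27ac peaks were largely shared. Of the WT H3K27ac peaks 24.1% (23.5 to 24.6) had no mutant peak, and of the mutant ones 18.4% (17.9 to 18.9) had no WT peak. H3K27ac at H3K4me3 sites was found in the mutant in 86.7% (86.1 to 87.3) of cases, and H3K27ac without H3K4me3 in 67.2% (66.4 to 68.0). These classes differed in score, with WT medians of 498.0 and 206.2. At like score the difference was -2.79 percentage points (-3.82 to -1.76). Median H3K27ac peak width was 1611 bp in WT and 1838 bp in the mutant.

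The WT H3K27ac peaks with the best scores and no mutant peak nearby included a pair on chromosome 2, from 26346463 to 26356511 (score 1679) and from 26337383 to 26344705 (score 1482). At these, mutant H3K4me1 covered 7662 and 6744 bp and mutant H3K79me2 10049 and 5822 bp. The adjoining WT H3K27ac peak, from 26356781 to 26360541 (score 1120, chosen after its values were seen), also had no mutant H3K27ac peak, while mutant H3K4me3 covered 3474 bp of it. Mutant H3K27ac peaks flanked these 3, from 26326968 to 26334505 and, within 1000 bp of the adjoining peak, from 26361012 to 26364605. The lists do not tell whether the acetylation was absent here or the peak was not called. On chromosome 2 from 127157438 to 127164395, mutant H3K4me3 covered 2676 bp, and a mutant H3K27ac peak lay within 10000 bp. On chromosome 1 from 45921875 to 45927310, no mutant list had a peak. In the mutant, the best H3K27ac peaks without a WT peak were on chromosome 11 from 119731238 to 119739904 (score 1328), chromosome 5 from 64731369 to 64736191, chromosome 2 from 46225221 to 46229286 and chromosome 19 from 11192781 to 11195861. WT cells had no peak of any mark at these regions except H3K4me1 over 1900 bp of the region on chromosome 5. Only the region on chromosome 11 had a WT H3K27ac peak within 10000 bp.

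**Figure D4:**
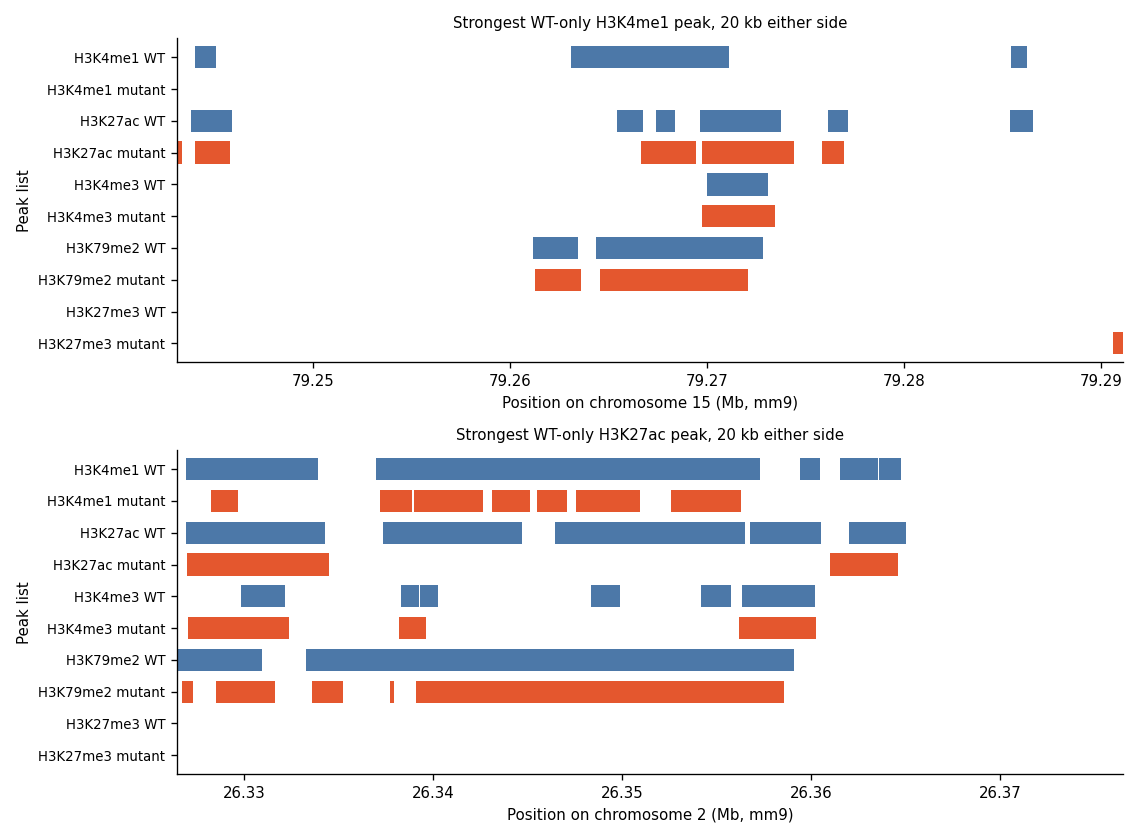
Bars are the peaks of each list along mm9 around the strongest WT-only H3K4me1 peak on chromosome 15 (top) and the strongest WT-only H3K27ac peak on chromosome 2 (bottom), with positions in Mb, WT in blue and mutant in orange. On chromosome 15 mutant H3K27ac lies under the WT H3K4me1 peak (4173 bp), and on chromosome 2 mutant H3K4me1 (7662 bp) lies where mutant H3K27ac has no peak.

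Large H3K27ac domains numbered 1314 in WT and 1240 in the mutant. Of the WT domains 99.7% (99.2 to 99.9) had a mutant H3K27ac peak, and 75.8% (73.4 to 78.1) overlapped a large mutant domain. Across the WT domains, H3K27ac covered 23.3 Mb in WT and 22.8 Mb in the mutant, while H3K4me1 covered 9.36 Mb in WT and 3.36 Mb in the mutant. Across the mutant domains, H3K27ac covered 20.8 Mb in WT and 24.2 Mb in the mutant, and H3K4me1 9.21 and 3.36 Mb. The direction for H3K27ac thus depended on the genotype that set the domains, and that for H3K4me1 did not. An H3K4me1 peak was in 87.1% of WT domains in WT and in 62.6% of them in the mutant. The mutant over WT ratio of domain counts was 0.944, and 1.06 with a stitching distance of 5000 bp.

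Large H3K27ac domains with no H3K27ac peak of the other genotype were few, 4 in WT and 7 in the mutant. The WT domains were on chromosome 11 from 87254886 to 87284709 and from 116167241 to 116191945, on chromosome 8 from 114377480 to 114400976 and on chromosome 18 from 5740632 to 5761049. H3K4me3 stayed in the mutant at the domain near 116 Mb of chromosome 11 (1210 bp) and at that of chromosome 8 (2626 bp). The longest mutant domains were on chromosome 8 from 119573514 to 119603146, where H3K27ac covered 15598 bp, and on chromosome 11 from 98981731 to 99010538, where it covered 9417 bp. WT cells had no active mark at these; H3K27me3 was there in both genotypes, over 1479 and 321 bp in WT and 964 and 3188 bp in the mutant. Further mutant domains lay on chromosome 10 from 76085052 to 76113520, chromosome 4 from 150059568 to 150087914 and chromosome 16 from 93188411 to 93216694. WT had H3K4me3 over 1308 bp and H3K79me2 over 525 bp of the domain on chromosome 10, and H3K4me1 over 1445 bp of that on chromosome 16. No WT list had a peak in the domain on chromosome 4.

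H3K4me3 was the most shared mark. Of the WT H3K4me3 peaks 11.3% (10.8 to 11.9) had no mutant peak, and of the mutant ones 6.18% (5.78 to 6.596) had no WT peak. All WT H3K4me3 peaks in the 4 strongest of 10 equal parts of the list by score had a mutant peak. Median H3K4me3 width was 1866 bp in WT and 2154 bp in the mutant, and broad H3K4me3 peaks numbered 840 and 1051. A broad mutant peak overlapped 80.7% (77.9 to 83.3) of the broad WT peaks. The WT share without a mutant peak was 7.17% with lists of the same number of strongest peaks.

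The strongest WT H3K4me3 peaks without a mutant peak nearby were on chromosome 11 from 119876099 to 119878807 (score 1057), chromosome 1 from 3659938 to 3662711, chromosome 15 from 85514277 to 85517335 and chromosome 4 from 125166878 to 125169723. Mutant H3K27ac was present on chromosome 11 (1698 bp) and chromosome 15 (2879 bp), and H3K27me3 covered the region on chromosome 4 in both genotypes. Only the region on chromosome 15 had mutant H3K4me3 peaks within 10000 bp. The strongest mutant H3K4me3 peaks without a WT peak were on chromosome 3 from 9942252 to 9945879 (score 1413), chromosome 1 from 173488830 to 173493288, chromosome 12 from 31758337 to 31761242 and chromosome 7 from 148154656 to 148157518. H3K27ac accompanied the mutant H3K4me3 on chromosomes 3, 1 and 7, and H3K27me3 that on chromosome 12. WT also had H3K27ac over 2605 bp of the region on chromosome 3 and H3K27me3 over 2226 bp of that on chromosome 12. No WT list had a peak in the regions on chromosomes 1 and 7.

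Bivalent regions numbered 2430 in WT and 2129 in the mutant, and 71.0% (69.1 to 72.8) of the WT regions had both H3K4me3 and H3K27me3 in the mutant. H3K27me3 without H3K4me3 was found in the mutant at 15.1% (13.7 to 16.6) of WT bivalent regions. At 4.86% (4.04 to 5.79) of them the mutant had H3K4me3 and H3K27ac without H3K27me3. Bivalent regions could also carry H3K27ac of their own genotype, as 741 in WT and 576 in the mutant did. The 4.86% is therefore not a share of regions that gained H3K27ac. Of the mutant bivalent regions, 81.1% (79.3 to 82.7) had both H3K4me3 and H3K27me3 in WT. WT had H3K27me3 without H3K4me3 at 7.37% (6.30 to 8.57) of them, and H3K4me3 and H3K27ac without H3K27me3 at 7.09% (6.04 to 8.27). The mutant over WT ratio of bivalent region counts was 0.876, and 1.23 with the still stricter threshold.

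H3K79me2 had fewer peaks in the mutant, 22103 against 26353, of like median width (1458 bp, and 1440 bp in WT). Of the WT H3K79me2 peaks 36.8% (36.3 to 37.4) had no mutant peak, and of the mutant ones 15.3% (14.8 to 15.7) had no WT peak. H3K79me2 peaks present in WT alone were short, with a median of 668 bp against 2626 bp for shared ones. H3K79me2 peaks of at least 10000 bp numbered 2051 in WT and 1698 in the mutant; mutant H3K79me2 covered 90.03% of the length of the WT ones.

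The longest WT H3K79me2 peak without mutant overlap was on chromosome 1 from 168950938 to 168972792 (21855 bp). Others lay on chromosome 13 from 34418063 to 34431409, chromosome 4 from 140191849 to 140205110, chromosome 8 from 97876348 to 97887466 and chromosome 14 from 71331298 to 71342392. Mutant H3K4me3 and H3K27ac were still present in the region on chromosome 4, at 1875 and 1556 bp. The longest mutant H3K79me2 peak without WT overlap was 4558 bp long, on chromosome 6 from 90674713 to 90679270. All 5 of the longest mutant regions had a WT H3K79me2 peak within 10000 bp, and 2 of the 5 WT regions had a mutant one.

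The strongest H3K79me2 peaks without a peak of the other genotype nearby were mostly short. In WT the best was on chromosome 17 from 30306255 to 30306645 (391 bp). WT H3K79me2 peaks on chromosome 13 from 29041438 to 29044872 and on chromosome 4 from 135699745 to 135701111 overlapped H3K4me3, H3K27ac and H3K27me3 in both genotypes. In the mutant the best was on chromosome 4 from 3662348 to 3662712 (365 bp), and all 4 had WT H3K79me2 within 10000 bp.

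The mutant H3K27me3 list was more extended, with 14712 against 13277 peaks and a ratio of covered length of 1.36. Its median −log10 q was also higher, at 4.18 against 3.89 in the WT list. A more sensitive mutant H3K27me3 library was not tested as a cause. Of the mutant H3K27me3 peaks 49.9% (49.1 to 50.7) had no WT peak, and of the WT ones 35.0% (34.2 to 35.8) had no mutant peak. H3K27me3 peaks of at least 10000 bp numbered 639 in the mutant and 337 in WT, and 638 of the 639 overlapped WT H3K27me3. WT H3K27me3 covered 79.7% of the length of the long mutant peaks, and mutant H3K27me3 98.3% of that of the long WT peaks. The WT share without a mutant peak was 22.4% with the still stricter threshold.

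The longest mutant H3K27me3 peaks without WT overlap were on chromosome 4 from 140459673 to 140470907 (11235 bp) and from 137272947 to 137281279, chromosome 15 from 80142886 to 80152247, chromosome 13 from 56078082 to 56086258 and chromosome 8 from 123578223 to 123585439. No other mark had a peak in these 5 regions in either genotype, and 4 of them had WT H3K27me3 within 10000 bp. In WT the longest was 4883 bp, on chromosome 6 from 4852246 to 4857128, where H3K4me3 was present in both genotypes. Others lay on chromosome 14 from 118441232 to 118445168, chromosome 15 from 98552216 to 98555846, chromosome 3 from 36734390 to 36737949 and chromosome 11 from 59988262 to 59991804. Mutant H3K27me3 lay within 10000 bp of 2 of these 5 WT peaks. The strongest unshared H3K27me3 peaks were shorter: in the mutant the best was on chromosome 4 from 133627014 to 133627246 (233 bp), and in WT on chromosome 2 from 16604699 to 16604915 (217 bp), where both genotypes had H3K27ac. All 4 of the strongest mutant peaks had WT H3K27me3 within 10000 bp, and 2 of the 4 strongest WT peaks had mutant H3K27me3.

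Stretches of at least 200 kb without any mark were about equal in number, 1844 in WT and 1855 in the mutant. Those with peaks of at least 3 marks in the other genotype numbered 59 in WT and 258 in the mutant. The WT lists held more peaks of each mark except H3K27me3, with 15981 against 5358 for H3K4me1. This makes 3 marks easier to reach in stretches bare in the mutant, and the counts of 59 and 258 were not adjusted for it. Of these stretches, 18 and 148 had 3 or more peaks of the other genotype wholly inside, and the others had fewer there. Peaks of the other genotype that only reached over an edge of a stretch also counted towards the 3 marks. A long stretch can thus be bare in both genotypes over most of its length. The longest in the mutant was on chromosome 6 from 73205232 to 81872998 (8.67 Mb), and only 2 WT peaks lay wholly inside it. Others lay on chromosome 8 from 98412632 to 105306631, chromosome 1 from 113761885 to 120205938, chromosome 19 from 48283160 to 53091149 and chromosome 14 from 106453775 to 111152742, with 2, 1, 3 and 2 WT peaks inside. In WT the longest was on chromosome 12 from 89689012 to 92606382 (2.92 Mb), with 2 mutant peaks inside, and the stretch on chromosome 16 from 46498610 to 48819805 held 7 mutant H3K27ac peaks. The most WT peaks in a stretch bare in the mutant were 14, on chromosome 5 from 113205065 to 113443543, with 5 H3K4me1, 3 H3K27ac, 5 H3K79me2 and 1 H3K27me3 peaks; this stretch was chosen after its values were seen.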

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

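No paired analysis was possible because each genotype had 1 library per mark and no result came from a test. Of 78 alternative values for the counts, lengths, shares and classes, 45 stayed within the limits set (1.5 times for a ratio, the 95% interval for a share), 31 moved beyond them and 2 crossed a ratio of 1; the cause was not tested. The intervals of shares are narrow, so small moves count. Depth limits are unknown here. The planned stricter threshold removed no H3K79me2 peak, so it says nothing about that mark, although its unchanged H3K79me2 values are among the 45. It also left the broad H3K4me3 peaks at 1051 in the mutant and 840 in WT. The gene lists were not run.

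The WT share without a mutant peak, for H3K4me1, H3K27ac, H3K4me3, H3K79me2 and H3K27me3 in turn, was 83.2, 26.99, 12.1, 52.3 and 46.0% when mutant peaks had to cover at least 50% of the WT peak. It was 71.9, 19.3, 9.95, 30.5 and 25.3% when a mutant peak within 1000 bp counted, and 57.0, 19.4, 7.17, 30.1 and 36.7% with lists of the same number of strongest peaks. The planned stricter threshold gave 78.1% for H3K4me1, 10.7% for H3K4me3 and 33.9% for H3K27me3. The still stricter threshold, chosen after seeing the data, gave 85.5% for H3K4me1, 9.48% for H3K4me3, 38.5% for H3K79me2 and 22.4% for H3K27me3. Under it the H3K4me1 ratios were 0.189 for peaks and 0.180 for length, that of active distal elements was 0.226, and that of bivalent regions crossed to 1.23. The ratio of large H3K27ac domains crossed to 1.06 with a stitching distance of 5000 bp.

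The ratio of active distal elements was 0.906 without the H3K4me1 libraries and 0.758 with the WT H3K4me1 list limited to its strongest peaks, both chosen after seeing the data. The share of WT H3K4me1 sites without a mutant peak that had mutant H3K27ac was 51.2% with the stricter threshold, 55.2% with overlap within 1000 bp, 56.3% with the still stricter threshold and 62.7% with the limited WT list. Of the 69 named regions and domains, 36 had a peak of the mark in the other genotype within 10000 bp.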

Other observations

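The tests of distal sites against H3K4me3 sites, of like-score sites on and off chromosome X, of H3K4me1 sites by class at like score and of the strongest 1%, and the descriptions of peaks found in a single genotype, were chosen only after the result was seen.

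H3K27ac peaks found in the mutant alone overlapped H3K4me3 of their own genotype less often than those found in WT alone. The shares were 8.73% (95% interval 7.88 to 9.63) of 4113 and 24.8% (23.7 to 25.9) of 6032. Over all H3K27ac peaks the shares were 44.0% in the mutant and 44.8% in WT. At like score, mutant H3K27ac peaks without H3K4me3 had a WT peak less often than those with it, by -19.6 percentage points (-20.4 to -18.7), where the same difference for WT peaks was -2.79. H3K27me3 was found in the mutant at 4.09% of the H3K27ac peaks of WT alone, and in WT at 2.29% of those of the mutant alone. Over all WT H3K27ac peaks, mutant H3K27me3 was found at 6.02% of those with H3K4me3 and 0.904% of those without. For mutant H3K27ac peaks and WT H3K27me3 the values were 5.37% and 0.599%. The difference between the shares for peaks of a single genotype thus also depends on how many had H3K4me3. These shares were not compared within such classes, so a gain of H3K27me3 at these peaks was not tested.

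The mutant library had fewer H3K4me1 peaks. Loss confined to weak WT peaks that fell below the caller's threshold is not the whole account. Of the strongest 10% of WT peaks 68.5% had a mutant peak, where over 90% was set for such a loss. A general drop in sensitivity can also remove strong peaks, so this value does not exclude one. Distal H3K27ac sites differed from H3K4me3 sites in the share kept by -2.22 percentage points (-3.87 to -0.565) averaged over score groups, short of the -5 set, but by -6.85 (-10.8 to -2.93) in the strongest group, which leaves a concentration there open. Lower sensitivity of the mutant library as the whole cause cannot be told apart from a true loss of H3K4me1. With 1 library per genotype, a true loss could also go with KMT2D or with any other difference between the WT and mutant cells. Of the strongest 10% of mutant peaks 5.60% had no WT peak, and of all mutant peaks 27.9% (49.3% of all had one when the WT list was cut to the same length). The value of 5.60% is under the 10% set for lower sensitivity before the run. That limit was dropped after the value was seen, since a true loss also leaves mainly WT sites. The share of WT peaks without a mutant peak was 5.00% in the strongest 1% and 31.5% in the strongest 10%, and sites without H3K27ac, H3K4me3 or H3K27me3 were kept less often than distal H3K27ac sites at like score, by -11.2 percentage points (-12.7 to -9.80) over 5 score groups and -9.58 (-11.1 to -8.11) over 20.

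Chromosome X had few H3K4me1 peaks, 7 in WT and 0 in the mutant, against 298 and 257 H3K27ac peaks. A complete absence of active elements on X does not account for this. H3K27ac peaks without H3K4me3 numbered 73 in WT and 59 in the mutant there. Such peaks were a smaller share on X, at 73 of 298 H3K27ac peaks against 13750 of 24759 on autosomes in WT. In the mutant they were 59 of 257 against 12463 of 22083. Their scarcity as a part of the cause was not tested. H3K4me3 peaks on X had lower scores: the median score of shared peaks on X was 0.494 times the autosomal one in WT and 0.593 times in the mutant. Having 1 copy of X could give lower scores, but the copy number was not examined and a score need not be proportional to it. Weaker X peaks are not enough to be the whole cause. Of autosomal WT H3K27ac peaks without H3K4me3 and of like H3K27ac score, 30.8% had H3K4me1, against 2.74% (0.334 to 9.55, 2 of 73) on X. What else lowers H3K4me1 on X was not tested.

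Mutant H3K27ac and H3K4me3 peaks were wider. Longer fragments in the mutant libraries could give this in all 3 MACS marks, and among peak pairs of like score the median difference, mutant minus WT, was 109 bp (90 to 124) for H3K27ac and 199 bp (185 to 216) for H3K4me3. For H3K4me1 it was 30 bp (-3 to 54, 273 pairs), an interval that includes 0 and lies below those of the other marks, so the shift was not alike in the 3 marks. The fragment length of each library is unknown, which leaves longer fragments in the H3K27ac and H3K4me3 libraries open. The genotype itself was not tested as a cause.

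Of 5012 WT H3K27ac peaks with the best scores, 8 had no mutant H3K27ac peak, and 7 of these (87.5%, 47.3 to 99.7) had mutant H3K4me3, H3K79me2 or H3K4me1. Of 4469 mutant peaks with the best scores, 29 had no WT H3K27ac peak. Any of these marks was found in WT at 10 (34.5%, 17.9 to 54.3) of the 29. Adjoining peaks on chromosome 2 are among the 8, so these are not independent cases. The unshared peaks also differed in class. Of such WT peaks, 3566 of 3573 with H3K4me3 and 1438 of 1439 without had a mutant peak. Of such mutant peaks, 2713 of 2716 with H3K4me3 and 1727 of 1753 without had a WT peak. The shares with other marks were not compared at like class.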
